A study of Homo sapiens with 8 samples.

How the data were processed

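Chromatin immunoprecipitation was done in OPM-2 cells after 72 h with DMSO, ATRA, POM or ATRA+POM, with 1 ChIP library and 1 input library per treatment. The 8 samples were grouped by the treatment and library kind in their labels. The files used were 4 peak lists, 1 per ChIP library, with 10 columns and no header. Chromatin was sheared and sequenced on a DNA nanoball platform per the labels' protocols. The genome build was hg38 per the submitters' processing notes. The aligner, the peak caller and their versions are not given in the sources used here, and neither is the antibody.

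The deposited lists give each peak a score, which is 10 times the −log10 p cut to a whole number. They also give a fold enrichment, which in the layout the authors used is a ratio of the summit to the local background of that library. The −log10 p and −log10 q of each peak are the authors' values as well, and no deposited peak had a −log10 p under 5. The authors called peaks per library, and no list pools libraries. Depth was not stated. Under a Poisson caller with a count of 1 added to reads and background, fold and p give the reads at the summit and the background. Reads came out whole within 0.02 for 100.0% of DMSO, 97.6% of ATRA-labelled, 100.0% of POM and 100.0% of ATRA+POM peaks. The lowest background value that occurred at least 20 times, divided by the smallest peak width as a stand-in for fragment length, gave the relative depth. The spacing of the background values gave the input reads at a summit. These are inferences from the values and are not stated by the submitters.

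Peaks on chromosomes 1 to 22 and X were used. Lists were compared by overlap of at least 1 bp, and shares carry 95% Wilson intervals. Peaks of all lists that shared a base were merged into regions, and the number of regions per set of lists was set against a model in which libraries differ in sensitivity and regions in how many libraries call them, with 1000 simulated draws. Peaks were ranked by −log10 q within a list.

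The gene table used has 19974 protein-coding genes of the same build with start and end but without strand or transcripts. The planned windows at transcription start sites were therefore replaced by windows of 1000 bp on each side of either annotated end of a gene, so that a start cannot be told from an end. The locus of a gene was its body with 5000 bp on both sides, in place of the upstream side alone. Peaks at a locus were counted as called, and neighbouring peaks were not merged for these counts. No genome sequence was used, so the planned search for 26 motifs was not run.

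For 29 gene lists the change in mean peaks per locus was ranked among 10000 random lists of the same size, matched on 10 strata of peaks per locus. The percentile describes these libraries and is not a p-value. Named genes follow a fixed rule: 16 genes always, the 10 strongest peaks called in a single list of each comparison with DMSO with the gene of the nearest end, and up to 4 members per list whose gene-end peak was called in a single list. The same was done for ATRA+POM against POM. Genes named outside this rule are said to be chosen after their values were seen, or hold the most regions of a set. The comparisons, lists and alternatives were fixed before the data were examined, except those said to be chosen later. The alternatives were the stronger 50% of each list, an equal number of 36742 peaks, an overlap of 50% of the peak, peaks within 500 bp as shared or merged, windows of 3000 bp and random lists matched on gene length. Added later were a fold enrichment of at least 10 and the patterns without the ATRA-labelled list.

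The steps were tested on simulated data. Overlap counts equalled those of a separate interval tool, 99.9% of 3000 simulated summit reads were recovered, and the model gave a mean ratio of 1.00 over 20 simulations of 60000 regions without a shared set and 1.47 with 4000 planted regions. The simulated regions followed the same kind of model. The ratio of 1.00 therefore checks the code and not whether the model suits these lists. Of 400 null lists 5.75% fell outside 2.5 to 97.5. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.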

Results

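OPM-2 is an established human myeloma cell line that carries the t(4;14) translocation, which brings NSD2 and FGFR3 under immunoglobulin control. The cells were grown for 72 h with the solvent DMSO, with 1 µM all-trans retinoic acid (ATRA, the ligand of the retinoic acid receptors), with 1 µM pomalidomide (POM, an immunomodulatory drug that makes the cereblon ubiquitin ligase degrade IKZF1 and IKZF3), or with both compounds. Chromatin immunoprecipitation with sequencing was done once per treatment, so 4 peak lists were compared. The labels do not name the antibody. The 4 matching input libraries were not used here beyond what the peak lists hold. There were no replicates, so no difference between treatments could be set against a spread, no test of a condition was made, and every interval covers counting error only.

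The lists held 50946 peaks with DMSO, 36742 in the library labelled ATRA, 54279 with POM and 47193 with ATRA+POM on chromosomes 1 to 22 and X. They covered 43.6, 23.4, 43.6 and 30.8 Mb, with median widths of 498, 385, 462 and 391 bp. The reads at the summit of a peak, recovered from its fold enrichment and its p, had a median of 78 with DMSO, 23 in the ATRA-labelled library, 72 with POM and 65 with ATRA+POM. Relative to DMSO, the sequencing depth behind the lists was 0.133 for the ATRA-labelled library, 0.927 for POM and 0.902 for ATRA+POM. The fold enrichment of a peak is the authors' own value for that library and was not scaled between libraries. Values set side by side are therefore descriptions and carry no direction.

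Peaks were concentrated at genes. A midpoint within 1000 bp of an annotated end of a protein-coding gene was found for 24.4% of DMSO peaks (95% Wilson interval 24.0 to 24.8), 30.4% of ATRA-labelled peaks (29.9 to 30.9), 22.6% of POM peaks (22.3 to 23.0) and 23.2% of ATRA+POM peaks (22.8 to 23.6). Such windows make up 2.40% of the sequence. Of 19974 protein-coding genes, 9756 had a peak at a gene end with DMSO, 7985 in the ATRA-labelled list, 9564 with POM and 8250 with ATRA+POM, and 7449 had one in all 4 lists. Genes that mark the plasma cell were among them in each list, including SDC1 (the surface proteoglycan CD138), TNFRSF17 (the receptor BCMA), CD38, IRF4 and IKZF3. The strongest peak at the TNFRSF17 locus on chromosome 16 had a fold enrichment of 94.5 with DMSO, 77.0 in the ATRA-labelled list, 115 with POM and 42.2 with ATRA+POM.

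The library labelled ATRA was compared with DMSO to ask what the retinoid alone did to the peaks. The loci of CYP26A1, DHRS3 and CYP26B1, which retinoic acid induces in many cell types, held no peak in it. CYP26A1, the enzyme that degrades retinoic acid (chromosome 10, 93073475 to 93077885), had 1 peak with DMSO and 0 in the ATRA-labelled list. DHRS3, a retinal reductase, and CYP26B1, a relative of CYP26A1 chosen after its values were seen, had 0 in both. RARB, the receptor gene named in the title of the series (chromosome 3, 24829321 to 25597932), had 18 peaks at its locus with DMSO and 13 in the ATRA-labelled list, and RARA had 13 and 8. Over the 34 retinoid genes the mean was 2.15 peaks per locus in the ATRA-labelled list and 2.94 with DMSO. Of the members 2 were higher and 14 lower (percentile 20.7). With an equal number of strongest peaks 6 were higher and 4 lower (percentile 50.8).

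Of the ATRA-labelled peaks, 120 (0.327%, 0.273 to 0.390) had no overlap with a DMSO peak. The strongest of them lay at ENSA (chromosome 1, 150621444 to 150621613), IQUB, FAM135A, TTC7B and GBP4, with 18, 18, 12, 12 and 11 summit reads, and none of the 120 reached a fold enrichment of 10. In the other direction 24820 DMSO peaks (48.7%, 48.3 to 49.2) had no ATRA-labelled counterpart. The strongest lay inside BICC1 (chromosome 10, 58757383 to 58757900, 326 summit reads), inside POT1, near the SLFN11 gene and beside TNFRSF10A, a receptor of the death ligand TRAIL. Gene-end peaks were called with DMSO and not in the ATRA-labelled list for 1778 genes, among them CRBN (cereblon, 46 summit reads), BCL2L11 (a pro-apoptotic BH3 protein, 91), BATF (93) and B2M (75), and for 7 genes in the reverse direction. The share of DMSO peaks that were also called in the ATRA-labelled list went from 2.78% in the weakest of 8 equal groups by summit reads to every peak in the strongest. Over all DMSO peaks it was 51.3%, where the depth of the ATRA-labelled library alone would let 66.0% pass. The shortfall was larger for the deeper lists. POM called 70.7% of DMSO peaks where depth would let 98.7% pass, and ATRA+POM 55.9% where it would let 98.5% pass. With an equal number of strongest peaks from each list, 656 peaks were called in the ATRA-labelled list alone, in place of 120.

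**Figure D1:**
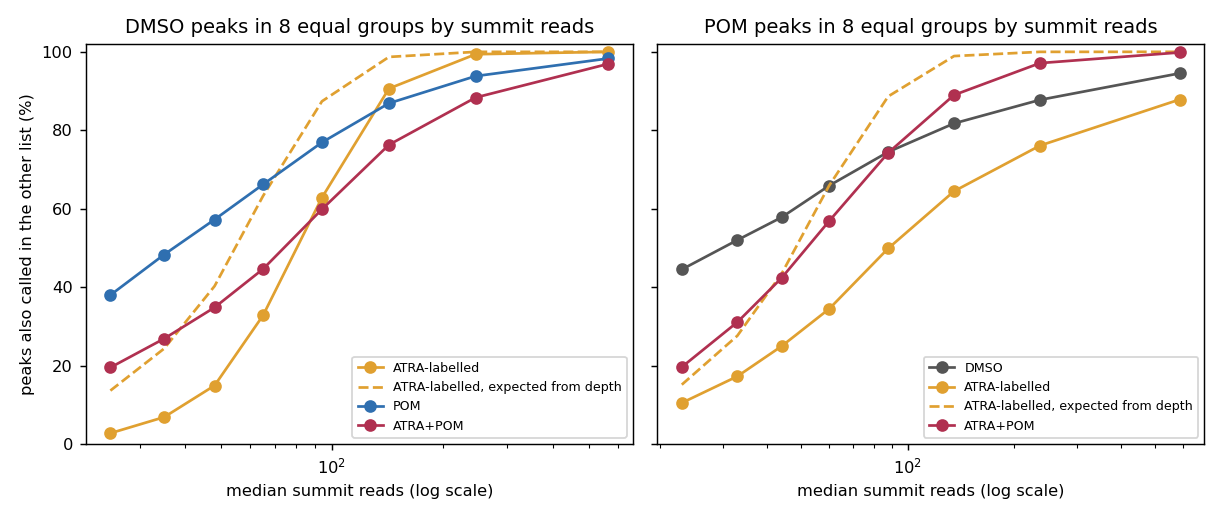
Percent of DMSO peaks (left) and of POM peaks (right) that were also called in each other list, against the median summit reads of 8 equal groups of peaks on a log axis; the dashed line gives the percent that the depth of the ATRA-labelled library alone would let pass. The share in the ATRA-labelled list went from 2.78% of the weakest DMSO peaks to all of the strongest, and reached 87.8% for the strongest POM peaks. Depth alone would let 98.7% of all DMSO peaks pass with POM and 98.5% with ATRA+POM, for which no line is drawn.

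Pomalidomide was compared with DMSO to ask what the drug alone did to the peaks. Gene-end peaks were called with POM and not with DMSO at 4 of 42 interferon-stimulated genes and at MICA, CD40 and TNFSF10. At RIGI, a sensor of viral RNA, a gene-end peak with 244 summit reads was called with POM and none with DMSO, and IFI6 had 119 reads, IFIT3 98 and USP18 21. MICA, a ligand of natural killer cells, had 63 reads, CD40, a receptor of B cells, 83, and TNFSF10, the death ligand TRAIL, 49, each with no peak at its locus with DMSO. The interferon list had 25 members with a gene-end peak with POM and 21 with DMSO, and its peaks per locus were higher for 11 members and lower for 8 (percentile 79.3, inside the middle 95%). Among antigen presentation genes 12 had one in each list, with MICA gained and HLA-B lost. KRT80, a keratin, had 7 peaks at its locus with POM and 0 with DMSO.

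In all, 16368 POM peaks (30.2%, 29.8 to 30.5) had no DMSO counterpart and 14923 DMSO peaks (29.3%, 28.9 to 29.7) had no POM counterpart. The strongest POM peaks without one lay inside RP1 (chromosome 8, 54665701 to 54668372, fold enrichment 139, 1572 summit reads), inside THSD4 on chromosome 15 (1730 reads), 107 kb from NFIB on chromosome 9 (1559), near PPP1R13B on chromosome 14 (1350) and near RAB7B on chromosome 1 (1311). Each of the 10 strongest was also called with ATRA+POM and was absent from the ATRA-labelled list. The strongest DMSO peak without a POM counterpart lay 68.9 kb from ANKRD7 (chromosome 7, 118310113 to 118313142, fold enrichment 81.2, 2327 reads). Among the 10 strongest were also peaks inside GUCY2F on the X chromosome (951), near LMO3 on chromosome 12 (1039) and near RCC2 on chromosome 1 (811). Others lay inside KMT2A, a histone methyltransferase (748), and inside BCL2, the anti-apoptotic protein (714). All 10 were also called in the ATRA-labelled list. Those inside HS2ST1 (957), 213 kb from LCORL (892) and 202 kb from CDH18 (858) were also called with ATRA+POM, and the rest of the 10 were not. Of the POM peaks without a DMSO counterpart 829 (5.06%, 4.74 to 5.41) were at a gene end, against 22.6% of all POM peaks and 2.40% of the sequence.

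At gene ends, 387 genes had a peak with POM and not with DMSO, of which 202 had no DMSO peak anywhere at the locus, and 579 had one with DMSO and not with POM. Apart from the list members, the former included KDR, the receptor of vascular endothelial growth factor (603 summit reads), and GCNT3 (576), chosen after their values were seen. The latter included TRIB3, a pseudokinase of the stress response with 5 peaks at its locus with DMSO and 0 with POM. The gene-end peak at IKZF1 was called with DMSO alone (1110 reads), but the strongest peak at the IKZF1 locus had 1431 reads with POM and lay farther than 1000 bp from the gene end. With an equal number of strongest peaks, 9722 POM peaks and 10552 DMSO peaks had no counterpart, which turns the order of the pair.

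The combination was compared with DMSO to ask what both compounds did together. CYP26A1 had a gene-end peak with a fold enrichment of 44.3 and 396 summit reads with ATRA+POM (chromosome 10, 93075518 to 93079063), against 4.16 and 45 reads with DMSO. DHRS3 had 5 peaks at its locus with ATRA+POM, 4 with POM and 0 with DMSO, RARG 13, 11 and 7, RARB 22, 23 and 18, and NRIP1, a nuclear receptor corepressor chosen after its values were seen, 7, 5 and 4. At the place of the strongest ATRA+POM peak of RARB the fold enrichment was 52.6 with ATRA+POM, 45.9 with POM and 16.1 with DMSO, and at that of RARG it was 40.0, 125 and 47.2. Over the 34 retinoid genes the mean number of peaks per locus was 3.62 with ATRA+POM, 3.29 with POM and 2.94 with DMSO, with 13 members higher and 5 lower from DMSO to ATRA+POM. That difference stood at percentile 99.5 among 10000 random lists matched on peaks per locus. At gene ends, 11 members had a peak with ATRA+POM and 13 with DMSO, and none had one with ATRA+POM alone.

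Of the ATRA+POM peaks, 11367 (24.1%, 23.7 to 24.5) had no DMSO counterpart. The strongest lay 14.7 kb from CD1D, which presents lipid antigens (chromosome 1, 158161946 to 158164716, fold enrichment 84.3, 2243 summit reads), 5.91 kb from PIK3CG, a phosphoinositide kinase of leukocytes (chromosome 7, 106857907 to 106860847, 149, 1391 reads), and inside AIG1 on chromosome 6 (1399 reads). CD1D stood apart from the other 9 strongest, which were also called with POM. The gene-end peaks of RIGI (128 summit reads), IFI6 (69), IFIT3 (30), MICA (23), CD40 (85) and TNFSF10 (45) that were called with POM were called with the combination too, and that of USP18 was not. Gene-end peaks at IDO1, the tryptophan-degrading enzyme, and IL26, a cytokine, were among the 10 strongest called with ATRA+POM and not with DMSO (358 and 312 reads), again chosen after their values were seen.

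In the reverse direction 22460 DMSO peaks (44.1%, 43.7 to 44.5) had no counterpart with ATRA+POM, and 1685 genes had a gene-end peak with DMSO and not with ATRA+POM against 179 the other way. Among the 1685 were BIRC5 (survivin, 182 summit reads with DMSO), E2F1 (149), MCM6, a part of the replicative helicase (172), and FZD2, a Wnt receptor (849). BIRC5, MCM6 and FZD2 had no peak at their loci with ATRA+POM and 2, 4 and 2 peaks with POM. ACTB had 4 locus peaks with DMSO, 2 with POM and 0 with ATRA+POM, and CD44, an adhesion receptor chosen after its values were seen, 6, 2 and 0. Of the 47 cell cycle genes, 41 had a gene-end peak with DMSO and 37 with ATRA+POM, and none gained one. The 4 of 41 that were without one compare with 17.3% of all genes that had one with DMSO, and the list's change in peaks per locus stood at percentile 31.8. The ATRA+POM list was also the shorter of the pair, and with an equal number of strongest peaks 14379 DMSO peaks were without a counterpart. At the 464 summits placed on the same base in both lists, the median log2 ratio of fold enrichment was −0.628 for ATRA+POM over DMSO. At the strong ones among them ATRA+POM had 0.499 of the DMSO reads. Losses at single genes therefore cannot be told apart from a lower enrichment over the whole ATRA+POM list.

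ATRA+POM was compared with POM to ask what the retinoid added to the drug. CYP26A1 had 2 locus peaks with POM, of which the gene-end peak had 52 summit reads, against the single ATRA+POM peak of 396 reads. CYP26B1 (chromosome 2, 72129238 to 72147862) had 2 locus peaks with ATRA+POM and none in the other lists. EXOC6B, which encodes a part of the exocyst and lies 28.1 kb from CYP26B1, had 15 peaks with ATRA+POM, 0 with POM, 3 with DMSO and 0 in the ATRA-labelled list. Its strongest (72202691 to 72206087) had a fold enrichment of 64.7 and 569 summit reads. Several of the 15 lay side by side between 72269586 and 72273042. Peaks with ATRA+POM and not with POM also lay near CD1D, 83.3 kb from NRIP1 (461 reads), near TRHDE (589) and inside CAMK1D (520), none of them called in any other list.

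**Figure D2:**
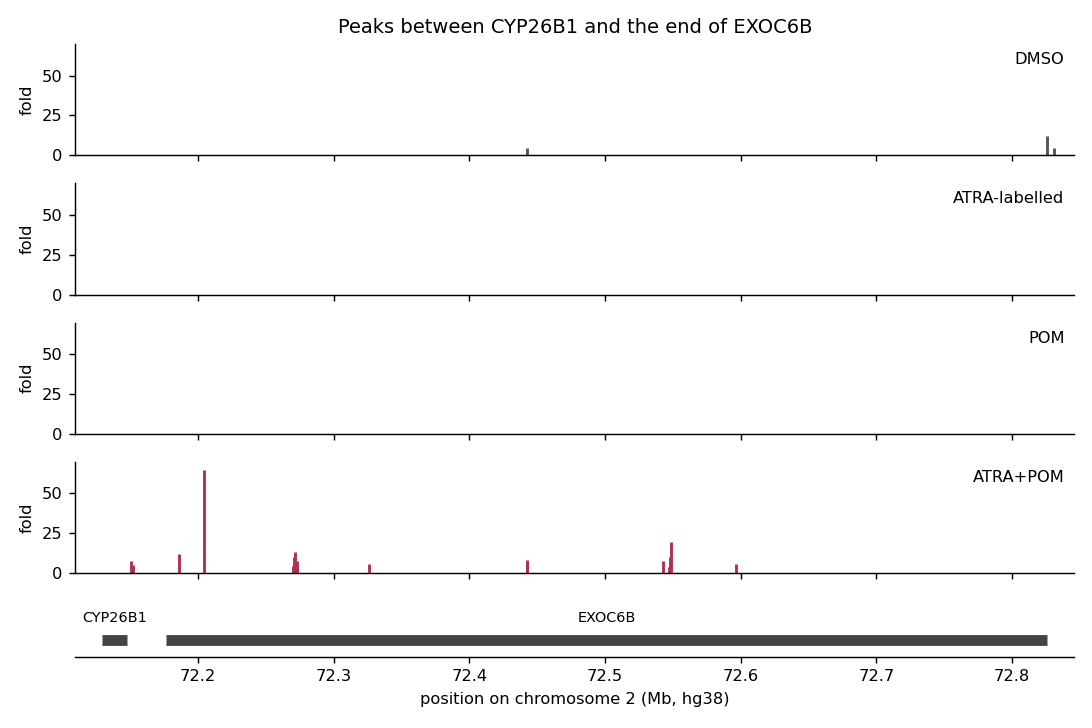
Peaks of the 4 lists on chromosome 2 from 72109238 to 72846033 (hg38), drawn at their midpoints with the authors' fold enrichment as height; gene bodies are drawn below. The window holds 3 DMSO peaks, 0 ATRA-labelled peaks, 0 POM peaks and 17 ATRA+POM peaks.

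In total 4944 ATRA+POM peaks (10.5%, 10.2 to 10.8) had no POM counterpart and 19662 POM peaks (36.2%, 35.8 to 36.6) had no ATRA+POM counterpart. The strongest of the latter lay inside ZBTB16 (chromosome 11, 114172708 to 114173712, 599 summit reads), a zinc finger protein that binds cereblon in the presence of such drugs. ZBTB16 had 9 locus peaks with DMSO, 6 in the ATRA-labelled list, 5 with POM and 2 with ATRA+POM. Gene-end peaks were called with ATRA+POM and not with POM for 68 genes, led by CD1D (406 reads), and with POM and not with ATRA+POM for 1382. At the 1333 summits placed on the same base in both lists, the median log2 ratio of fold enrichment was −0.716 for ATRA+POM over POM. A lower enrichment over the whole ATRA+POM list cannot be told apart from losses at single genes here either. Over the retinoid list the change from POM to ATRA+POM stood at percentile 98.5.

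ATRA+POM was last compared with the ATRA-labelled library, which asks what the drug added to the retinoid. Without a counterpart were 20679 ATRA+POM peaks (43.8%, 43.4 to 44.3) and 8561 ATRA-labelled peaks (23.3%, 22.9 to 23.7). CYP26A1, DHRS3, CYP26B1, EXOC6B and CD1D each had peaks at their loci with ATRA+POM and 0 in the ATRA-labelled list. The reads of the CYP26A1 peak, scaled to the depth of the ATRA-labelled library, would come to 58.3, above the 23 of that library's median peak. Those of the strongest DHRS3 and CYP26B1 peaks would come to 15.4 and 6.18. The median is not the calling limit, since summit reads in that list had a 10th percentile of 11 and a minimum of 5. The scaled DHRS3 reads lie above both values, and the scaled CYP26B1 reads lie between them.

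Peaks of the 4 lists merged into 67328 regions, and 19384 were called in all 4. Among regions called in a pair of lists alone, 6464 were called with POM and ATRA+POM, 5044 with DMSO and POM, 2769 with DMSO and in the ATRA-labelled list, 718 with DMSO and ATRA+POM, 10 in the ATRA-labelled list and with POM, and 2 in the ATRA-labelled list and with ATRA+POM. A model in which libraries differ only in sensitivity gave ratios of observed to expected regions of 2.17 (2.11 to 2.22) for POM with ATRA+POM, 3.65 (3.52 to 3.79) for DMSO with ATRA-labelled, 0.681 (0.662 to 0.700) for DMSO with POM, 0.264 (0.245 to 0.284) for DMSO with ATRA+POM, 0.0120 (0.00577 to 0.0221) for ATRA-labelled with POM and 0.00655 (0.000793 to 0.0237) for ATRA-labelled with ATRA+POM. The intervals are exact Poisson intervals of the observed number.

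The locus of HDAC5, a histone deacetylase gene on chromosome 17, held the most regions called with POM and ATRA+POM alone, 15 within 56.9 kb. It had 21 peaks with POM and 19 with ATRA+POM against 3 with DMSO and 4 in the ATRA-labelled list. NSMCE2 and RIMS2 on chromosome 8 held the most regions called with DMSO and in the ATRA-labelled list alone, 7 each. Regions called with POM and ATRA+POM alone lay at a gene end in 2.80% of cases (2.43 to 3.23), against 33.7% (33.1 to 34.4) of regions called in all 4 lists. Those called with DMSO and in the ATRA-labelled list alone were also low, at 5.38% (4.60 to 6.28). Since POM and ATRA+POM were set against the same DMSO list, gains overlap without an effect. Regions gained with POM and with ATRA+POM numbered 6478, where the model gave 3643. Independent lists spread over all 67328 regions would give 2389. That value counts regions called with DMSO, which cannot be gained, so it is too low and no excess is read from it. The model holds the same DMSO list, so its 3643 already includes an overlap from the shared control. What gave the excess over the model cannot be told from these numbers.

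**Figure D3:**
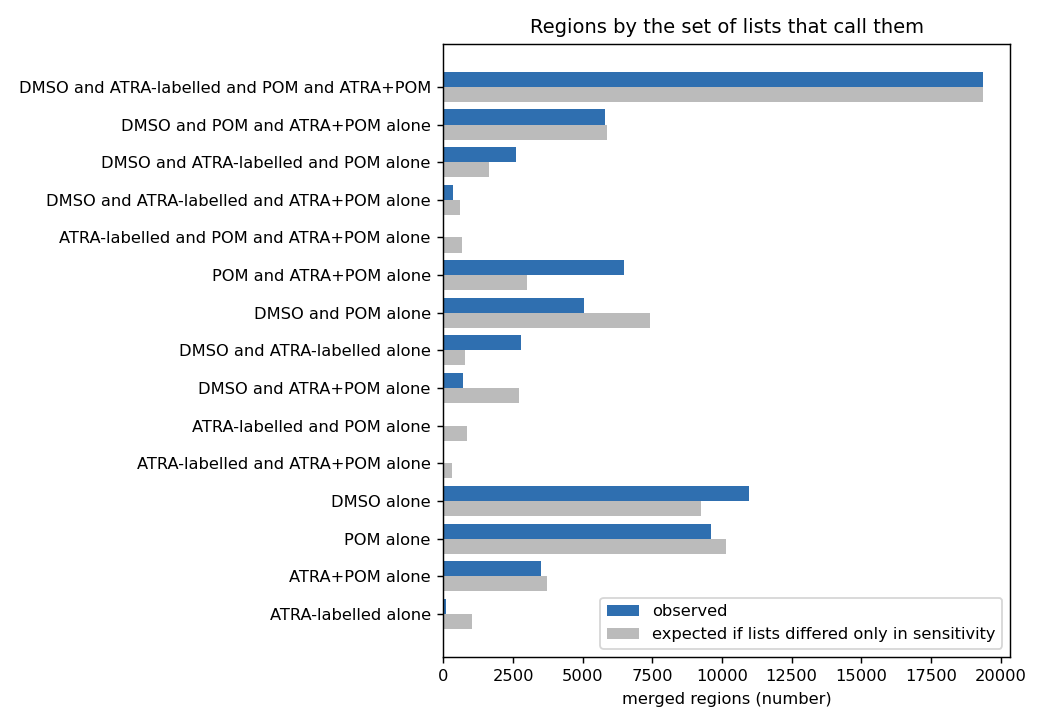
Number of merged regions (bars, linear axis) by the set of lists that call them, observed (blue) and expected from a model in which the lists differ only in sensitivity (grey). Regions of POM and ATRA+POM alone number 6464 against 2984 expected, and regions of ATRA-labelled and ATRA+POM alone 2 against 305.

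The genes fixed for all libraries differed in how they stood across the lists. Among genes of the cereblon pathway, CRBN had 2 locus peaks with DMSO, 0 in the ATRA-labelled list and 2 each with POM and ATRA+POM, while IKZF3 had 14, 12, 15 and 16. IRF4, on which myeloma cells depend, had 8, 5, 4 and 4 peaks, and MYC 6, 5, 3 and 4. Of the translocation partners NSD2 had 10, 15, 11 and 12 and FGFR3 4, 2, 4 and 3. Of the receptors RARA had 13, 8, 10 and 15 and RXRA 7, 5, 11 and 8. SDC1 had 6, 7, 6 and 7, TNFRSF17 2, 3, 2 and 2 and CD38 3, 3, 3 and 2. Among the other myeloma transcription factors, chosen after their values were seen, MAF had 6, 6, 12 and 15 peaks, BACH2 12, 11, 18 and 17, MEF2C 15, 9, 9 and 6 and POU2F2 3, 0, 0 and 0.

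Over the 29 gene lists and 3 comparisons with DMSO, 12 of 87 percentiles lay outside the middle 95%, where random lists give 4.35. With POM it was the keratin list, with 7 members higher and 1 lower. Matched on gene length it came inside at 96.2 and the ribosomal protein list went outside at 98.1, and with an equal number of peaks the HOX list did at 98.3. With ATRA+POM they were the retinoid list, the 42 interferon-stimulated genes (14 members higher and 3 lower, percentile 99.1) and the 84 ribosomal protein genes (34 and 24, 98.2). With an equal number of strongest peaks, the ribosomal list stood at percentile 56.6, with 21 members higher and 30 lower, and the interferon list at 92.5 (95.6 when matched on gene length). The other 8 belong to the ATRA-labelled library. They were high for ribosomal protein, histone, mitochondrial ribosomal protein, chromatin regulator, proteasome and cell cycle genes (99.6 for the mitochondrial ribosomal list) and low for HOX genes (1.42) and the markers of T and NK cells (0.585). Matched on gene length, the mitochondrial ribosomal (91.1), cell cycle (92.6), proteasome (93.2) and T and NK (2.70) lists came inside the middle 95%, and with an equal number of peaks the mitochondrial ribosomal (96.2) and HOX (6.65) lists did. In that library 0 of 20 T and NK markers had more locus peaks than with DMSO and 6 had fewer, among them LCK with 6 peaks with DMSO and 0 in the ATRA-labelled list. The cereblon list stood inside the range in all 3 comparisons, at percentiles 73.4, 8.89 and 16.0 for the ATRA-labelled library, POM and ATRA+POM.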

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

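The tests of lower depth, of a shared input, of cells without retinoic acid, of a preparation batch and of chance among the lists were chosen only after the results were seen. In data that no comparison used, 2 contigs outside the chromosomes analysed held 5 peaks each with ATRA+POM and 0 with DMSO. One contig belongs to chromosome 14 (5 peaks) and the other to no known chromosome (5 peaks). Neither held a peak in the POM or the ATRA-labelled list, and no explanation was tested.

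Of the ATRA-labelled peaks 99.7% were called with DMSO, 87.8% with POM and 76.9% with ATRA+POM. Of the 634 summits shared with DMSO, 224 had whole input reads in both lists, and these were equal at 193 (86.2%), against at most 13.2% (14 of 106) in any other pair, which would follow if both lists were called against the same input. The variance of the summit reads was 2.83 times that of a random part of the DMSO reads, which argues against such a part. Set against independent Poisson counts it was 2.07 times, under the 32.4 to 128 of the other pairs. Among those pairs, ATRA-labelled with POM and with ATRA+POM had only 5 and 10 strong summits. Of 193 ATRA+POM peaks in neither the DMSO nor the POM list that were strong enough to pass at its depth, 0% were called in it, against 87.6% of those in both, a value that the overlap with DMSO gives by itself. Each of the 193 had at least a 95% chance to pass at that depth. Their absence argues against lower depth alone for these 193 peaks. Over the whole list, lower depth, cells without retinoic acid, a wrong label and a retinoid effect that needs the drug cannot be told apart.

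Regions were shared by the POM and ATRA+POM lists alone more often than the model gave. The DMSO library was the deepest of the 4. With the stronger 50% of each list the ratio was 2.16. That cut raises the threshold in every list, so a peak in the weaker 50% of a list counts as absent. The ratio therefore cannot decide on weak calls. Of the strongest of 8 equal groups of POM peaks by summit reads, 94.5% were called with DMSO and 99.8% with ATRA+POM. A preparation batch shared by POM and ATRA+POM cannot be told apart from the drug, because each treatment has 1 library. The larger ratio of DMSO with either list was 0.681. The model keeps the number of regions called in 2 lists, so an excess in some pairs lowers the ratios of others. The value of 0.681 therefore does not decide on a batch. Without the ATRA-labelled list the ratio was 1.86. That the drug changes the signal at these regions stays a hypothesis, which replicate libraries that cross preparation and drug would decide.

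Retinoid gene loci held more peaks with ATRA+POM by the number of peaks called. Peaks of that list were narrower, with a median width of 391 bp against 498 bp with DMSO. A broad peak split into several would also raise the number, and this was not tested. Without RARG, the member with the largest change, the list stood at percentile 98.3, which argues against a single locus. From POM to ATRA+POM it stood at 98.5, which argues against a change wholly present with POM alone, although 0.353 of the change of 0.676 peaks per locus was there with POM. Chance among the lists cannot be told apart, since 12 percentiles lay outside the middle 95% where 4.35 would by chance, and 8 of them belong to the ATRA-labelled library. A direct action of retinoic acid at CYP26B1 and DHRS3 may be part of the change and was not tested by motif. DHRS3 had 0 locus peaks with DMSO, 4 with POM and 5 with ATRA+POM. CYP26A1 had 1, 2 and 1, so it added none to the change in number, although its ATRA+POM peak was the stronger.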

How the results depend on the processing

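No paired analysis was possible because each treatment has 1 ChIP library. Motif enrichment with its variants and the alternative on soft-masked repeats were not run, for want of a genome sequence. A fold enrichment of at least 10 and the patterns without the ATRA-labelled list were chosen after seeing the data. Counts moved both ways, and the cause was not tested.

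Peaks in 1 list and not the other, with the stronger 50% of each list, were: ATRA-labelled not DMSO 30, DMSO not ATRA-labelled 10444, POM not DMSO 7443, DMSO not POM 6377, ATRA+POM not DMSO 6098, DMSO not ATRA+POM 10523, ATRA+POM not ATRA-labelled 10166, ATRA-labelled not ATRA+POM 4527, ATRA+POM not POM 2386, POM not ATRA+POM 8699. With a fold of at least 10 they were 0, 2276, 3637, 1835, 2303, 3890, 4418, 2056, 333 and 2330 in that order. With an equal number of strongest peaks, ATRA-labelled not DMSO was 656, DMSO not ATRA-labelled 11185, POM not DMSO 9722, DMSO not ATRA+POM 14379, ATRA+POM not ATRA-labelled 13666 and POM not ATRA+POM 9941. ATRA-labelled not DMSO was 188 with an overlap of 50% of the peak and 52 with peaks within 500 bp shared.

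Gene-end genes of ATRA-labelled not DMSO were 1 with the stronger 50% and 40 with an equal number, and those of ATRA+POM not DMSO 311 with 3000 bp. Gene-end shares with 3000 bp were 33.2, 41.7, 31.8 and 32.7% for DMSO, ATRA-labelled, POM and ATRA+POM. With the stronger 50% they were 31.3, 31.7 and 27.5% for the first 3, and with an equal number 28.1, 25.8 and 23.7% for DMSO, POM and ATRA+POM.

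Ratios with an equal number were POM with ATRA+POM 2.43, DMSO with ATRA-labelled 3.06, DMSO with POM 0.479, DMSO with ATRA+POM 0.214, ATRA-labelled with POM 0.0500 and with ATRA+POM 0.0352. With the stronger 50%, DMSO with ATRA-labelled was 3.32 and with ATRA+POM 0.207. With peaks merged within 500 bp, POM with ATRA+POM was 2.07, DMSO with ATRA-labelled 4.16 and with POM 0.592. Without the ATRA-labelled list, POM with ATRA+POM was 1.86, DMSO with POM 0.898 and with ATRA+POM 0.334. With an equal number, DMSO not POM (10552) passed POM not DMSO, and the mean change turned sign for 16, 10 and 3 of the 29 lists in the ATRA-labelled library, with POM and with ATRA+POM. Of the lists outside the middle 95% these were cell cycle (−0.0213 to 1.17) and mitochondrial ribosomal genes (−0.0135 to 0.365) in the ATRA-labelled library and ribosomal genes with ATRA+POM (0.214 to −0.0833). Of the list percentiles outside the middle 95%, 7 came inside on the same side with lists matched on gene length and 5 with an equal number. Others went outside. Matched on gene length, these were plasma cell markers (1.195), zinc finger genes (1.73) and chromatin regulators (98.3) with ATRA+POM, ribosomal genes with POM (98.1), zinc finger (1.79) and olfactory receptor genes (98.3) in the ATRA-labelled library, and from POM to ATRA+POM the Wnt (1.95) and olfactory receptor lists (99.4). With an equal number they were HOX genes with POM (98.3), and myeloma transcription factors (98.3), the unfolded protein response (99.7), zinc finger (1.89) and keratin genes (98.0) in the ATRA-labelled library. The keratin list from POM to ATRA+POM, the lowest of its random lists, stood at 50.1 when matched on gene length.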

Other observations

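Among markers of T and NK cells, 1 of 20 had more locus peaks with ATRA+POM than with POM and 8 had fewer (percentile 1.74, but 5.86 when matched on gene length, inside the middle 95%). LCK, a kinase of T cell signalling, had 5 with POM and 0 with ATRA+POM. Histone genes stood at percentile 99.6 and the 40 chromatin regulators at 98.1 (93.0 with an equal number of peaks) in the same comparison, with 25 and 20 members higher and 16 and 13 lower.

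Of ATRA+POM peaks strong enough to pass at the depth of the ATRA-labelled library, 1 of 1848 called with POM and not DMSO was also called there, and so were 27 of 68 called with DMSO and not POM and 13226 of 15104 called with DMSO and POM. The names of the peaks in the DMSO and ATRA-labelled lists share a letter code that the other lists lack. The input samples have no list of their own and were not analysed here.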
